A study of Mus musculus with 6 samples.

How the data were processed

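RNA of sorted mouse cortical astrocytes was sequenced in 6 libraries, 3 from animals given clozapine-N-oxide (CNO) and 3 from animals given saline. Per the labels' protocols, 10 ng of total RNA per library went into a high-sensitivity kit with single indices. The deposited table holds 1 column per library and 24421 genes, all columns matched a library by name, and 0 columns were left without one. Per the submitters' processing notes, the tools were Trimmomatic 0.4, FastQC 0.10.1, MultiQC 0.9, STAR 2.5.0a and DESeq2 1.20.0, and the genome build was mm10. The role of each tool, the read counter, the gene annotation and strand handling are not given in the sources used here, so genes that overlap or have near-identical copies may share reads.

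The deposited values are a signal, read counts per gene that the authors had divided by 1 size factor per library. In each library, 100% of the values were whole multiples of 1 step, within a tolerance of 1e-06 reads, and whole reads were recovered by dividing by that step. A single read was worth 4.23 normalized counts in CNO 1 and 0.503 to 0.970 in the other 5 libraries. Recovered totals ran from 3908076 reads in CNO 1 to 19224186 in CNO 2. The reads carry no molecular identifiers, so a floor of 3 reads for a count of 0 covers counting error only. Folds given as at least a value rest on this floor and do not allow for other losses of transcripts. That floor, 3 reads per library, averaged 5.94 normalized counts over the CNO libraries.

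Groups and replicate numbers were taken from the labels. The labels do not say whether libraries came from separate animals or from pools, so the p-values measure only the spread between these libraries. The test of each gene used limma 3.58.1 in R 4.3.3 on log2 of the normalized count with a pseudocount of 1, so fold changes are differences between mean log2 values. For genes at 0 reads in some libraries of a group these can exceed the ratio of means or differ from it in sign, as for Uty (log2 fold change -5.23, ratio of means 1.17). It ran on the 13028 genes with a mean of at least 10 over the 6 libraries, with a variance trend (eBayes, trend on), 2-sided tests and Benjamini-Hochberg adjustment at 0.05. Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, where at least 5 members were tested. Of 31 lists, 28 met this. The mitochondrially encoded list had 0 members in the table, the ependymal and choroid plexus list had 4 tested members and the erythroid list 1. Each list median was also placed among the medians of 10000 random lists, drawn for each member from the 100 genes nearest in mean level. These percentiles describe the libraries and are not tests across replicates. Cell type lists were compared by the mean log2 value and by the share of reads per library, each with an exact permutation test over the 10 splits, which cannot go below p = 0.1.

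Genes named in the text followed a rule fixed before the data were examined. Per direction it took up to 12 genes with the largest change among those with an adjusted p under 0.05, a mean of at least 50 in the higher group and no overlap between groups. If fewer than 5 passed in a direction, up to 8 genes with the smallest unadjusted p were named and said not to pass. Up to 4 members with the smallest p were eligible from each list, and 12 genes were always eligible, and predicted gene models were not named. Some eligible genes are not reported here. Coordinates are those of the GENCODE mouse release 21 on GRCm38, the same assembly as mm10, and 12550 of the 13028 tested symbols had a match in it.

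Alternatives were pseudocounts of 0.5 and 8, other filters, quantile and TMM scaling, array weights, no variance trend, each library left out, limma-voom, edgeR 4.0.16, DESeq2 1.42.0, and other thresholds. The recovered reads served edgeR, limma-voom and DESeq2. Added after the data were seen were a filter on genes with a read in every library, a covariate for high or low Xist, list statistics without their trend with level (with the preset and with an estimated correlation), and DESeq2 on all genes. With the Xist covariate the gene test still compared CNO with saline, while camera compared high with low Xist. The method was tested on simulated data with the means and depths of these libraries. With the real spread and 12319 tested genes, it recovered 3% of genes changed 4-fold and 37% of genes changed 16-fold, with 5 false calls. With a low spread it recovered 100% of both, with 8 false calls among 12945 tested genes. The simulation gave both groups the same spread per gene and no trend with level. The real CNO libraries differed more from one another than the saline libraries, so these rates need not hold here. Figures were drawn with matplotlib 3.10.9.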

Results

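Cortical astrocytes that carry CD51 (integrin alpha V) were labelled in CD51-Flp mice by a viral vector that expresses hM3D and mCherry under the GFAP promoter after Flp recombination. hM3D is a Gq-coupled designer receptor that CNO activates. Animals received CNO or saline 2 times per day from postnatal day 7 to 21, and mCherry-positive cells were sorted on day 21. The comparison asks which transcripts differ in these sorted cells between animals given CNO and saline. With no CNO group lacking the receptor, effects of CNO apart from the receptor cannot be told from Gq activation. CNO 1, 2 and 3 held 3908076, 19224186 and 17102657 reads, and saline 3, 4 and 5 held 17389282, 12010901 and 19052161.

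The clearest difference lay in myelin transcripts. Mbp, which encodes myelin basic protein, rose in the CNO libraries to 2420700 ± 733830 normalized counts from 517550 ± 78379 in saline (mean ± SD, n = 3 each), a ratio of means of 4.68. Mobp, which encodes another protein of compact myelin, rose to 174530 ± 47657 from 33877 ± 6547.5, a ratio of 5.15. Mbp accounted for 15.6% ± 5.65 of all reads in CNO and 5.35% ± 0.875 in saline. Both genes were higher in every CNO library than in any saline library. They were the 2 genes of 13028 that passed the threshold in limma, with log2 fold changes of 2.19 ± 0.22 (SE, adjusted p = 0.00692) for Mbp and 2.35 ± 0.26 (adjusted p = 0.00926) for Mobp. Mbp lies on chromosome 18 at 82475146 to 82585637 and Mobp on chromosome 9 at 120149707 to 120181484 (GRCm38, protein-coding genes). The median log2 fold change over all tested genes was -0.89, and relative to it Mbp stood at 3.07 and Mobp at 3.23. That median was -0.09 among genes with a read in every library and 0.004 in DESeq2. The relative values therefore depend on genes with zeros and on the method. Genes of a higher level had higher fold changes in these libraries, and above that trend Mbp stood at 0.79 and Mobp at 1.30. That trend was fitted with both genes included. At the level of Mbp it reached 1.39, while genes with a mean of at least 10000 had a median of 0.60. The 0.79 of Mbp may therefore depend in part on Mbp itself.

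Of the 12 oligodendrocyte markers, 2 rose over all genes in limma and 10 did not pass, while 8 were higher and 1 lower when adjusted over the list alone. Mal, a membrane protein of myelin, averaged 21040 ± 9391.9 in CNO and 6024.4 ± 1743.5 in saline (limma adjusted p = 0.488). The list as a whole ranked above other genes (camera adjusted p = 1.4e-04 with the preset correlation, adjusted p = 0.765 with an estimated correlation). No test of this list for CNO adjusted for Xist level was obtained, and it did not pass with quantile scaling (adjusted p = 0.154). Its median log2 fold change was 1.70, against 0.34 for lists of the same expression level. The list took 18.2% ± 6.71 of reads in CNO and 6.43% ± 1.30 in saline, without overlap (exact permutation p = 0.1, the smallest possible, adjusted p = 0.55), and most of this share was Mbp. Their mean log2 level, 11.77 ± 1.26 in CNO and 11.26 ± 0.72 in saline, overlapped between groups (exact permutation p = 0.6, adjusted p = 0.66), and the difference fell from 0.51 to -0.003 without CNO replicate 2. Log2 fold changes were above 0 for 8 of the 12 markers and below 0 for 4.

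**Figure D1:**
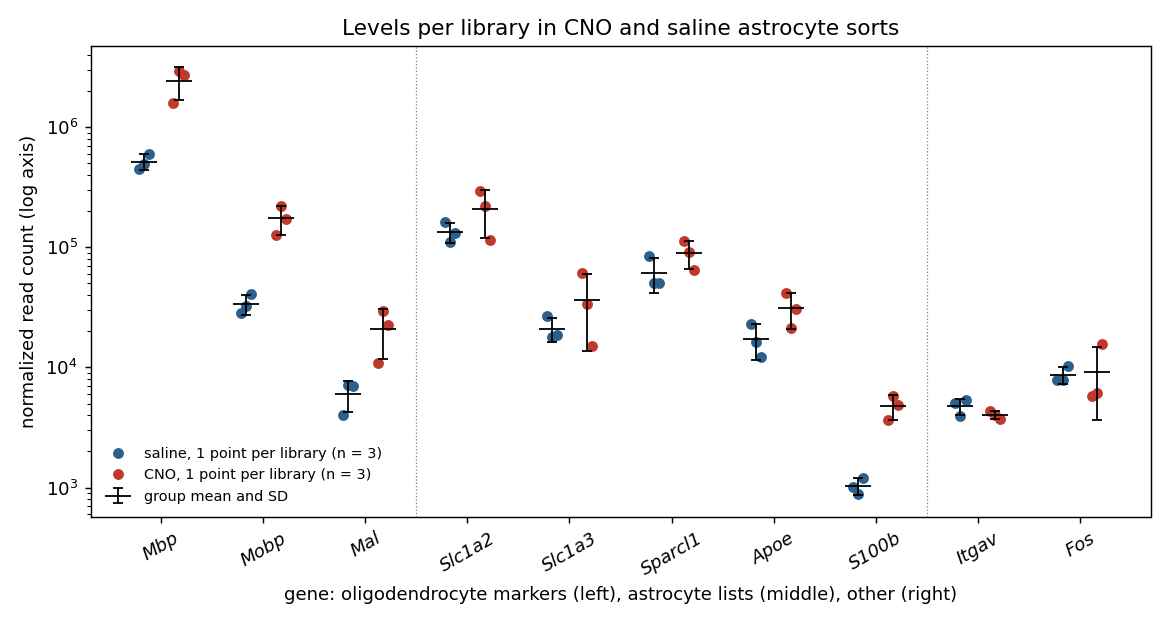
Normalized read counts (log axis) of oligodendrocyte markers, members of astrocyte lists and 2 other genes, with 1 point per library and bars for mean and SD (n = 3). All 3 CNO libraries lie above all 3 saline libraries for Mbp, Mobp, Mal and S100b, while the groups overlap for Slc1a2, Slc1a3, Sparcl1, Apoe, Itgav and Fos.

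Next by unadjusted p among the genes higher in CNO, none past the threshold in limma, were Pkp4, Prr18, Trak2, Plekhb1, Fth1, Bcas1, Ankrd40 and Rims2. Pkp4, a plakophilin, averaged 29220 ± 5448.7 against 6248.2 ± 1362 (limma adjusted p = 0.0839). Prr18 averaged 9588.6 ± 3412.1 against 1419.4 ± 408.16, and Fth1, the ferritin heavy chain, 38400 ± 11298 against 10330 ± 5009.2. The log2 fold changes of the 8 ran from 1.95 for Plekhb1 to 2.72 for Prr18.

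No gene passed as lower in CNO with limma, where 944 genes were lower and 297 higher at an unadjusted p under 0.05, while edgeR called 0 lower with the same filter and 3 without it, and DESeq2 180 with the filter and 478 on all genes. Those with the smallest p in limma, none past its threshold although DESeq2 called all 8, were Cxcl9, Pot1b, Ckap2l, Pstk, C3, Homez, Icos and H2-Ab1. C3, complement component 3, had 0 reads in each CNO library and 186.54 ± 62.2 normalized counts in saline, at least 31.4-fold lower. Icos was likewise at least 32.2-fold lower and Ckap2l at least 41.5-fold lower. H2-Ab1, an MHC class II chain, averaged 2.96 ± 5.13 in CNO and 620.2 ± 463 in saline. Fewer genes were detected in the CNO libraries, 10159 ± 1717 against 13607 ± 221 with every library thinned to 3908076 reads (exact permutation p = 0.1). Among genes with a mean of 100 to 300, 34.1%, 3.56% and 12.1% were at 0 reads in CNO 1, 2 and 3, and 0.687% to 1.22% in the saline libraries. The median log2 fold change was -2.33 for genes with a mean of 10 to 50 and 0.60 for those of at least 10000, and -0.09 among the 7395 genes with a read in every library. Each CNO library correlated more closely with every saline library than with another CNO library (Spearman over tested genes, 0.558 to 0.667 within CNO, 0.635 to 0.755 between groups and 0.798 to 0.819 within saline). Of the tested genes, 2222 (17.1%) had no overlap between groups, where chance gives 10%.

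**Figure D2:**
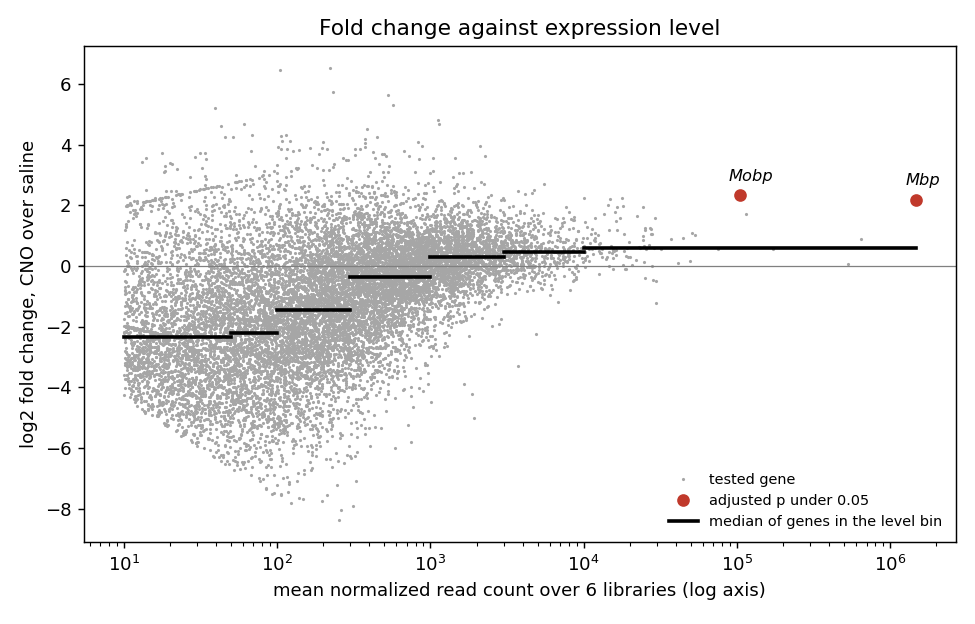
Log2 fold change of CNO over saline against the mean normalized read count (log axis), with 1 point per tested gene and black lines for the median in each level bin. The medians climb from -2.33 at means of 10 to 50 to 0.60 at 10000 or more, and Mbp and Mobp, in red, are the 2 genes past the threshold.

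Transcripts of astrocytes themselves were abundant in both groups, but so were those of other cell types. Astrocyte markers had a mean log2 level of 12.66 in CNO and 12.28 in saline. Microglia and macrophage markers had 11.77 and 12.07, and the oligodendrocyte list took more reads than the astrocyte list. Changes in the lists therefore cannot be assigned to astrocytes alone. None of the 20 astrocyte markers passed over all genes in limma, and 1, S100b, was higher when adjusted over the list alone. S100b, a calcium-binding protein, averaged 4782.1 ± 1101.9 in CNO and 1031.4 ± 169 in saline (limma adjusted p = 0.488). Its log2 fold change of 2.20 ± 0.48 lay closer to the 2.19 of Mbp than to the median of the astrocyte list. Whether its rise came from astrocytes was not tested. Slc1a2, the main glutamate transporter of astrocytes, averaged 209670 ± 89329 and 134860 ± 26093. Slc1a3 had a log2 fold change of 0.60 ± 0.44 and Aldh1l1 of 0.42 ± 1.11. Gfap averaged 338.6 ± 532 and 729.3 ± 504, with values from 4.23 to 952 in CNO. The astrocyte list took 3.01% ± 1.51 of reads in CNO and 3.05% ± 0.582 in saline (exact permutation p = 1, and p = 0.6 for the mean log2 level). Its median log2 fold change of 0.49 ranked above other genes in camera (adjusted p = 0.00186, adjusted p = 0.765 with an estimated correlation) and lay close to the 0.52 of lists matched on level. The direction of this list turned with quantile scaling (adjusted p = 0.722) and without the trend with level (adjusted p = 0.568). In the model with an Xist covariate, camera tested high against low Xist rather than CNO against saline. There the list ranked lower in the libraries with high Xist (camera adjusted p = 0.00831).

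A further 7 lists passed camera with the preset correlation, and none of the 9 did so with an estimated correlation (adjusted p from 0.765 to 0.898). No member of these 7 passed in limma over all genes or adjusted over the list alone. Ribosomal proteins had a median log2 fold change of 0.57 (adjusted p = 3.3e-09), with Rps29 at 0.99 ± 0.32. Factors acting on synapses had a median of 0.32 (adjusted p = 0.00278), with Hepacam at 1.32 ± 0.56, Cd38 at 1.48 ± 0.66, Sparcl1 at 0.55 ± 0.28, Gpc4 at 1.01 ± 2.45 and Thbs1 at -5.57 ± 2.06. Transmitter uptake and ion homeostasis had a median of 0.29 and a mean of -0.10 (adjusted p = 0.0157), with Abat at 1.52 ± 0.52 and Gabbr1 at 1.25 ± 0.48. Cholesterol synthesis (median 0.05, mean -0.08, adjusted p = 0.0178), lipid handling (0.16 and -0.35, 0.0178) and the nuclear-encoded respiratory chain (0.04 and -0.23, 0.00735) ranked above other genes although their means lay below 0. Hmgcs1, which starts sterol synthesis, had 1.45 ± 0.38, Insig1 1.33 ± 0.52, Scd1 1.36 ± 0.48, Apoe 0.86 ± 0.34, Ndufa4 1.55 ± 0.62 and Cox6a1 0.91 ± 0.36. Cell cycle genes ranked below other genes (median -2.27, adjusted p = 0.0386), beside -1.52 for lists matched on level. Prc1 had 0 reads in every CNO library and was at least 17.9-fold lower, and Mcm3, at 0 reads in CNO 1 and 3, had -6.46 ± 2.11 with a ratio of means of 0.0350. Lists matched on level had medians of 0.30, 0.13 and 0.29 beside ribosomal proteins, synapse factors and transmitter uptake, and of -0.17, 0.09 and -0.47 beside cholesterol synthesis, lipid handling and the respiratory chain. Without the trend of the statistics with level, ribosomal proteins (adjusted p = 0.0186) and the respiratory chain (adjusted p = 0.0308) still passed, and 0 lists did so with an estimated correlation. Synapse factors (0.727), transmitter uptake (0.577, direction turned), cholesterol synthesis (0.155), lipid handling (0.660) and cell cycle genes (0.333) no longer passed. With the Xist covariate, camera tested high against low Xist, so its results for these 7 lists do not address CNO against saline. Lists on synapses, transmitter uptake and cholesterol ranked lower in high Xist (camera adjusted p = 0.0376, 1.91e-04 and 0.0255).

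Lists closest to receptor activation did not pass in the main test. The 35 immediate early and activity-induced genes had a median log2 fold change of -0.46, against 0.09 for lists matched on level (camera adjusted p = 0.965, ranked up), with 0 members passing in limma over all genes and 0 adjusted over the list alone. Without the trend with level, the direction turned and the list passed as lower (adjusted p = 8.66e-04 with the preset correlation, adjusted p = 0.844 with an estimated correlation). Fos, an immediate early gene, averaged 9224 ± 5600.5 in CNO and 8642.7 ± 1422.9 in saline. Nr4a1 averaged 542.7 ± 149 and 2054.7 ± 216, and Egr2 averaged 208.6 ± 96.9 and 912.9 ± 138, without overlap and without passing in limma (adjusted p = 0.488 for both). The 58 calcium and Gq signalling genes had a median of -0.71 (adjusted p = 0.873), and none passed in limma over all genes or adjusted over the list alone. In this list, Itpr2 had -0.39 ± 0.49, Rgs2 -1.31 ± 0.72, Rcan1 -1.63 ± 1.30, Chrm3 -0.62 ± 0.63, Camk2d -2.12 ± 0.76 and Calm3 2.42 ± 0.88, and Ryr3 was at least 16.4-fold lower. Itgav, the gene of CD51, averaged 4022.6 ± 336 in CNO and 4759.2 ± 741 in saline (log2 fold change -0.23 ± 0.39, adjusted p = 0.822).

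No other list passed camera, and apart from 1 in each of the precursor and sex-linked lists no member passed in limma adjusted over the list alone. Median log2 fold changes were -1.01 for reactive astrocyte genes, -0.70 for integrins and matrix (Timp3 at 1.76 ± 0.53), -0.57 for glycolysis (Pfkfb3 at -1.65 ± 0.69) and -1.09 for interferon genes, whose member Psmb9 was at least 9.25-fold lower. They were 0.21 for heat shock (Hsp90ab1 at 1.02 ± 0.31), -0.60 for the unfolded protein response, -0.70 for glucocorticoid-responsive genes, -0.03 for astrocyte transcription factors and -1.11 for Notch, BMP and Hedgehog genes (Notch1 at -2.22 ± 0.89). Reactive astrocyte genes moved down on balance in fry (adjusted p = 0.0176), a test that does not compare them with other genes. Their median of -1.01 was not below the -1.15 of lists matched on level.

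**Figure D3:**
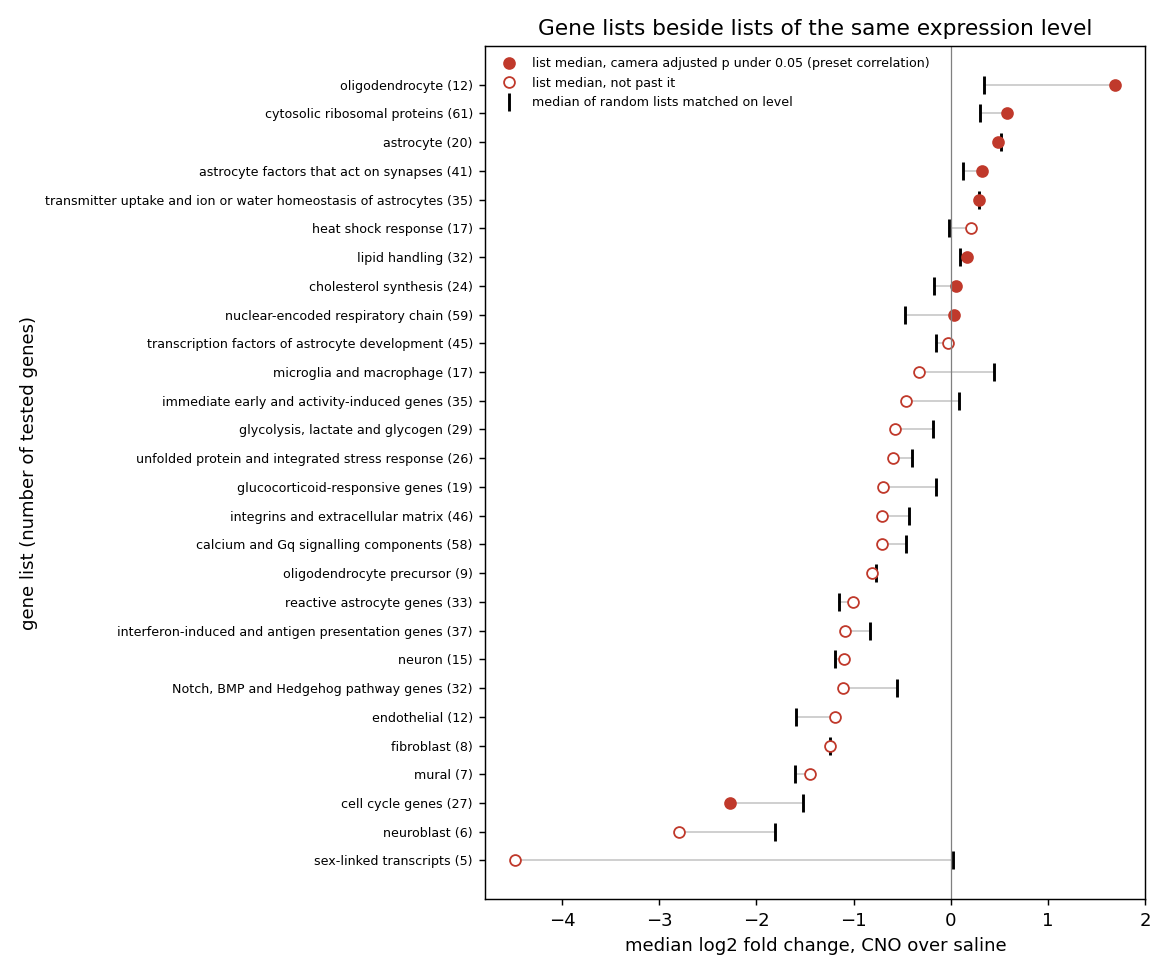
Median log2 fold change of each of the 28 tested lists (circles, filled where camera with the preset correlation passed) beside the median of random lists of the same level (bars). The oligodendrocyte list stands at 1.70 against 0.34, and the astrocyte list at 0.49 against 0.52.

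Markers of several other cell types were detected, while the erythroid list had 0 reads in all 3 CNO libraries. Microglia and macrophage markers took 1.06% ± 0.419 of reads in CNO and 1.54% ± 0.269 in saline (exact permutation p = 0.3, and p = 0.6 for their mean log2 level), with a median log2 fold change of -0.33 against 0.44 for level-matched lists. Within this list, Mrc1 averaged 38566 ± 15417 and 17603 ± 3562.5, Pf4 averaged 4988.7 ± 630 and 1732 ± 752, and Trem2 averaged 350.1 ± 24.9 and 966.4 ± 372, none past the threshold in limma. Precursor markers had a median of -0.81, with Olig1 at 2.10 ± 0.61 and higher when adjusted over the list alone. Medians were -1.10 for neurons, -2.80 for neuroblasts (-2.64 with members at 0 set to their bound), -1.19 for endothelial, -1.45 for mural and -1.24 for fibroblast markers. Read shares went the other way for neuroblast markers, 0.0113% ± 0.00612 in CNO and 0.00730% ± 0.000328 in saline (exact permutation p = 0.4). The share of precursor markers also averaged higher in CNO, 0.0445% against 0.0300% (exact permutation p = 0.5). Shares of neuron, endothelial, mural and fibroblast markers averaged lower in CNO. Mean log2 levels of the neuroblast, ependymal and erythroid lists did not overlap between groups (exact permutation p = 0.1, adjusted p = 0.367). Sex-linked transcripts differed between libraries of both groups. Xist stood at 25.4, 21466 and 35033 in CNO 1, 2 and 3 and at 216, 35117 and 885.3 in saline 3, 4 and 5, and Y-linked Ddx3y at 2417.2, 6.7 and 1.9 and at 1451.8, 212.9 and 1954.7. Xist exceeded 10000 in 2 CNO libraries and 1 saline library, so this class was not balanced between groups, and saline 4 held high Xist together with Y-linked transcripts. Kdm5d, also Y-linked, was lower when adjusted over the list alone (-6.10 ± 1.84), at 4.2, 6.7 and 1 in CNO 1, 2 and 3. The list median was -4.48. Ddx3y and Uty were at or near 0 in CNO 2 and 3, the 2 CNO libraries with high Xist, and not in CNO 1 (ratio of means 1.17 for Uty). This list therefore cannot be read apart from the Xist class of the libraries.

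The 2 calls were lost with any 1 of the 6 libraries left out, with a mean filter of 50, with quantile scaling, without the variance trend, with only genes read in every library and in edgeR with the same filter, each of which gave 0 calls. edgeR without a filter gave 16 calls and DESeq2 249, 69 higher and 180 lower, and both included Mbp and Mobp. Of the named genes that limma did not call, DESeq2 called Pkp4, Prr18, Trak2, Ankrd40, Rims2 and S100b as higher and Ryr3, Prc1, Kdm5d and the 8 genes lower by smallest p as lower. On all genes, DESeq2 also called Nr4a1, Thbs1 and Psmb9 as lower. limma-voom called Mal, Pkp4, Prr18, Trak2, Plekhb1, Fth1 and Bcas1 as higher, and so did array weights apart from Mal.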

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

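Added after the data were seen were the filter on genes with a read in every library, the Xist covariate, the list statistics without their trend with level (with the preset and with an estimated correlation), and DESeq2 on all genes. The counts of genes moved most. Against 2 calls, both higher in CNO, array weights gave 11 higher and limma-voom 16 higher. edgeR without a filter gave 16, of which 13 were higher and 3 lower, DESeq2 249 (69 higher, 180 lower) and DESeq2 on all genes 555 (77 higher, 478 lower). Calls fell to 0 (0 higher) with a mean filter of 50, quantile scaling, no variance trend, edgeR with the filter, genes with a read in every library, and any 1 library left out (0 to 0). The log2 fold change of Mbp was 2.01 without CNO replicate 2 to 2.46 without CNO replicate 1, so the calls ended through wider error or adjustment. It was 0.87 with quantile scaling, where Mbp, ranked 1 to 3 in each library, has little room to differ. The pseudocounts, TMM, no filter, the fold limit and the Xist covariate kept both calls. Of 13028 genes, 3 passed at an adjusted p under 0.1. Lists past the threshold numbered 9, and 0 with quantile scaling or an estimated correlation (with or without the trend with level), 1 with fry, 2 with genes read in every library, and 4 to 10 with 1 library left out (4 without CNO replicate 1 or 2, 5 without saline replicate 5). The oligodendrocyte and ribosomal lists passed in 16 of 21 alternatives, counting the Xist covariate, whose list test did not compare CNO with saline. Cell type lists without overlap numbered 3, and 1 with a pseudocount of 8 or quantile scaling, and 3 to 9 with 1 library left out (9 without CNO replicate 3). Of 1388 values of named genes under the alternatives, 1297 kept direction and side of the threshold, 55 newly passed, 22 no longer passed and 14 changed sign. Sign changes were Slc1a2 (-0.82), Slc1a3 (-0.20) and Sparcl1 (-0.70) with quantile scaling, Fos (0.074 in edgeR without a filter, 0.096 in DESeq2, 0.094 in DESeq2 on all genes), and Aldh1l1 (-0.12) and Gpc4 (-0.61) with the Xist covariate. With 1 library left out, Fos ran from -0.52 to 0.20, Gpc4 from -0.33 to 3.66 and Aldh1l1 from -0.57 to 1.24. Of 583 list values, 397 kept direction and side, 7 newly passed, 67 no longer passed and 112 differed in direction against other genes, given here with adjusted p. These counts include the run with the Xist covariate, where camera tested high against low Xist. The list values of that run are therefore not results for CNO against saline. Opposite to the main CNO direction in it were calcium and Gq (0.604), synapse factors (0.0376), transmitter uptake (1.91e-04), integrins (0.308), cholesterol (0.0255), cell cycle, glucocorticoid and neuroblast (0.695), glycolysis (0.179), respiratory chain (0.182), interferon, ribosomal, precursor and microglia (0.690), transcription factors (7.65e-04), lipid handling (0.0723), astrocyte (0.00831), endothelial (0.682), mural (0.973) and fibroblast (0.675). With quantile scaling the lists that changed direction were immediate early (0.0534), calcium and Gq (0.602), synapse factors (0.896), transmitter uptake and transcription factors (0.645), integrins and glycolysis (0.375), heat shock and astrocyte (0.722), glucocorticoid (0.456), microglia (0.0740) and mural (0.834). Without the trend with level they were immediate early (8.66e-04), calcium and Gq and glucocorticoid (0.478), transmitter uptake (0.577), integrins (0.549), glycolysis (0.361), transcription factors (0.912), astrocyte (0.568), neuroblast (0.875), microglia (0.00109) and mural (0.860), and with an estimated correlation besides immediate early, calcium and Gq, glucocorticoid and microglia (0.844), integrins (0.848), glycolysis (0.855), transmitter uptake, astrocyte, neuroblast and mural (0.923) and transcription factors (0.965). In fry, whose direction is not relative to other genes, they were immediate early and fibroblast (0.498), calcium and Gq (0.140), integrins (0.166), glycolysis (0.628), glucocorticoid (0.253), transcription factors (0.769), neuron (0.846), precursor (0.838) and microglia (0.869). With edgeR ranks they were immediate early (0.682), calcium and Gq, glucocorticoid and microglia (0.762), integrins (0.845) and glycolysis, unfolded protein and Notch (0.987), and with genes read in every library immediate early (0.390), calcium and Gq and glucocorticoid (0.625), integrins (0.738), glycolysis (0.690), unfolded protein (0.616) and microglia (0.862). With a pseudocount of 8 they were immediate early (0.851) and glycolysis, unfolded protein and mural (0.990), with no filter immediate early (0.901) and unfolded protein (0.961), with a mean filter of 50 immediate early and unfolded protein (0.624) and glycolysis (0.880) and with array weights immediate early and integrins (0.885) and mural (0.969). With 1 library left out, the adjusted p of lists that turned ran as follows: immediate early 0.187 to 0.954, calcium and Gq 0.630 to 0.992, integrins 0.274 to 0.992, glycolysis 0.122 to 0.970, unfolded protein 0.571 to 0.970, glucocorticoid 0.450 to 0.875, transcription factors 0.0222 to 0.838, Notch 0.602 to 0.968, precursor 0.373 to 0.970, microglia 0.0908 to 0.919, endothelial 0.0209 to 0.954, mural 0.528 to 0.965, fibroblast 0.507 to 0.988. The cause of these changes was not tested beyond the values given. No paired analysis was possible because the groups share only replicate number 3. Depth limits CNO 1 most, where 1 read is worth 4.23 normalized counts.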

Other observations

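Tests here were chosen after the results were seen, except those of shared zeros, of border macrophage markers and of zeros among DESeq2 calls higher in CNO, which were written down before their values were computed. The explanations offered are hypotheses.

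Beside lists of the same expression level, 3 lists lay in the highest 2.5% (oligodendrocyte at percentile 100, the respiratory chain at 99.3 and ribosomal proteins at 99.2) and 3 in the lowest 2.5% (immediate early genes at 0.96, microglia and macrophages at 0.02 and sex-linked transcripts at 0). Without their trend with level, the statistics of the oligodendrocyte list (camera adjusted p = 1.2e-09), ribosomal proteins (adjusted p = 0.0186) and the respiratory chain (adjusted p = 0.0308) ranked higher. Those of immediate early genes (adjusted p = 8.66e-04), microglia (adjusted p = 0.00109) and sex-linked transcripts (adjusted p = 0.00171) ranked lower. In the planned test none of these 3 passed, and immediate early genes and microglia had the opposite direction. The sex-linked list cannot be read apart from the unbalanced Xist classes of the groups. All 6 calls used the preset correlation, and none was kept with an estimated correlation (adjusted p from 0.844 to 0.848).

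The 2 limma calls, the 9 lists and the 249 DESeq2 calls each have 10 splits of the 6 libraries, too few for a share under 0.05. At least as many limma calls came in 1 of the 10 splits, the real one, and the highest other split gave 1 call. At least as many lists came in 2 of them, and another split gave 10 lists. At least as many DESeq2 calls came in 1, with 69 in the highest other split.

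The first pattern is the higher level of oligodendrocyte transcripts. The shallow CNO 1 is argued against, since the log2 fold change of Mbp without it was 2.46. Scaling stays open, because the lowest value of Mbp over quantile and TMM scaling was 0.87, and quantile scaling leaves the top-ranked gene little room. A larger share of oligodendrocyte or myelin RNA in the CNO sorts is a candidate explanation. The 10 other tested oligodendrocyte markers had a median log2 fold change of 1.63, where the highest 2.5% of level-matched lists lie above 0.80. However, 4 of the 10 were below 0, and their mean log2 level with Mbp and Mobp overlapped between groups. The mCherry gate should remove such cells, yet their RNA was present in saline also. There the oligodendrocyte list took 6.43% of reads and the astrocyte list 3.05%. Messengers carried into myelin processes exceeded other myelin genes by only 0.26 in median log2 fold change. That list held Mbp and Mobp, the 2 calls to be explained, so the excess cannot tell process fragments from whole cells. A response to CNO was not tested apart from these.

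The second pattern is the smaller number of genes detected in the CNO libraries. Depth is argued against, since at equal depth the CNO libraries still had 3448 fewer genes on average, without overlap. A few dominant genes are argued against likewise, at 3350 fewer genes without Mbp, Rn45s and Malat1. Random loss of rarer transcripts before sequencing may contribute: among 3489 genes with a saline mean of 100 to 300, pairs of CNO libraries shared zeros 1.64 times as often as independent losses would give, and 51 genes were at 0 in all 3 CNO libraries against 8.10 from independence. The pair ratio lay under the limit set beforehand for random loss. That limit was applied to pairs, and the excess in all 3 libraries was larger, so random loss alone is not shown. With genes taken by their mean over all libraries, the ratio was 1.10 and the counts 10 and 4.72. That mean includes the CNO values, so a gene at 0 in all 3 CNO libraries needs a higher saline level to enter. Shared zeros are thus fewer by selection, and this ratio cannot speak for independent losses. The CNO libraries also agreed less with one another (Spearman up to 0.667) than with saline (from 0.635 to 0.755, each CNO library closer to every saline library), so differences between groups rest on CNO libraries that stand apart, which was not tested as a cause. The labels give 10 ng of input RNA for every library, so unequal nominal input has no support, while the quality of the RNA, its loss during preparation and true lower expression of some of these genes stay open.

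The third pattern is the gap between DESeq2 and limma. Of the 69 DESeq2 calls higher in CNO, against 2 in limma, 26.1% had 0 reads in at least 1 library (95% binomial interval 16.3 to 38.1), beside 43.2% of all tested genes. This lies between the limits set beforehand, over 50% if zeros drive these calls and under 20% if not, so the test cannot decide. For the 180 calls lower in CNO, few CNO reads follow from the selection of lower genes, and loss of rarer transcripts was not separated from lower expression.

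A hypothesis on macrophages found no clear answer. Mrc1 and Pf4 averaged higher in CNO, neither past the threshold in limma, while the microglia list lay low. This could come from more border macrophage RNA. The 9 further border macrophage markers had a median log2 fold change of 0.15, between the median of -0.01 for level-matched lists and 0.67, above which the highest 2.5% of them lie, so the test cannot decide. Lyve1 stood at 1.19 ± 0.42 and F13a1 at 1.12 ± 0.50, and Ms4a7 at -1.41 ± 1.62. The sort should remove these cells, yet Mrc1 averaged 17603 normalized counts in saline, beside 21062 for Slc1a3.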
